A study of Zea mays with 18 samples.

How the data were processed

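The study measured polyadenylated RNA of isolated maize cells (Zea mays, inbred line B73) by sequencing. Per the labels, the cells fall into 6 groups of 3 libraries: sperm cells, egg cells, zygotes collected 12 h and 24 h after pollination, and the apical and basal cells that the first division of the zygote yields. The abbreviation hap in the labels was read as hours after pollination. Each library was made from few cells with a low-input cDNA amplification kit, per the labels' protocols: 1000 sperm cells, 20 egg cells, 14 to 15 zygotes at 12 h, 16 to 17 zygotes at 24 h, 16 apical cells and 13 to 14 basal cells.

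The authors deposited a table of raw counts per gene ID, whole numbers that had not been normalised. Per the submitters' processing notes, FastQC, cutadapt 1.13, Trimmomatic 0.32, STAR 2.5.2a, featureCounts and DESeq2 were used with the genome build B73 RefGen_v3. The strand setting and the treatment of reads that map to several genes are not given in the sources used here, so genes with near-identical copies and genes that overlap on opposite strands are uncertain. The table held 39475 gene IDs and 0 rows that name no gene. All 18 columns of counts carried the name of their library, and 0 further columns of samples were present. Gene names came from a table of reference genes of the assembly Zm-B73-REFERENCE-NAM-5.0, which pairs 18907 of the IDs with a reference gene and 2520 with an informative name. It matched 521 IDs to more than 1 gene, and these stayed unnamed. Coordinates are not given because that assembly is not the build of the counts. A looser naming rule was tried after the counts of 4 genes had been seen and was not used.

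Depth ranged from 11128444 to 25771168 counts per library. Reads were amplified without molecular identifiers, so counting intervals and floors cover counting error only. For a group with 0 counts of a gene, folds are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. The chi-square check of count differences between libraries of a group, over genes with a count of at least 20, found no pair that differed by as little as sampling noise. The labels do not say that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

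The samples, comparisons, tests, detection limits, the rule for named genes, 22 gene lists and most alternatives were chosen before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersions, TMM scaling, filterByExpr), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Sperm was compared with egg in a fit of all 18 libraries. The 5 other comparisons came from a fit of the 15 libraries without sperm, in which 5 groups share 1 estimate of the spread. In all, 6 comparisons were made: sperm with egg, 12 h zygote with egg, 24 h with 12 h zygote, apical cell with 24 h zygote, basal cell with 24 h zygote, and apical with basal cell. Values are TMM-normalised CPM, that is counts scaled to library size, as mean ± SD over 3 libraries. A ± after a log2 fold change is an approximate standard error, the absolute fold change over the square root of the F statistic of the test. CPM printed within a comparison come from its own fit, with TMM factors and library sizes taken over the genes left after filterByExpr. CPM of the detection results, of single libraries, of courses over all 6 groups and in the plots of genes come from all 18 libraries, with TMM factors and library sizes taken over all genes before that filter, so they differ somewhat from those of the fits for the same gene and group.

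A gene counted as detected with at least 1 CPM in all 3 libraries of a group and as not detected with under 0.1 CPM in all 3. Genes detected at 12 h but in neither gamete, and genes detected in sperm and at 12 h but not in egg, also had to be higher at 12 h than in egg. Named genes are the 6 with the largest fold change in each direction among called genes whose groups do not overlap, with at least 10 CPM in the higher group and an informative name, the called member of each list with the smallest adjusted p in each direction, and the 5 with the highest level at 12 h in each detection result. Genes named outside this rule were chosen after their values were seen, and the text says so.

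Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), which ranks a list against all other tested genes, with an estimated correlation and fry as alternatives. Of the lists fixed beforehand, most held few members because the reference gave few descriptions, and 3 had at least 5 tested members: embryo patterning transcription factors, heat shock proteins, and wounding and defence genes. A further 33 lists were written from reference symbols after the totals and correlations of the libraries had been seen and before any comparison, and 32 of them had enough members. The 35 lists were adjusted together within each comparison, and smaller lists give values only. The rule for named genes was applied to the later lists as well.

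Alternatives were RLE, upper-quartile and library-size-only scaling, other filters, DESeq2 1.42.0, limma voom with quality weights, fits of only the 2 groups compared or of all 18 libraries, other thresholds, the replicate number as a block, and leaving out each library. The list tests without egg replicate 1 and without apical replicate 1 were added after seeing the data. The fits were tested on simulated data with 200 genes changed by known folds in counts drawn from the means of these libraries. The changed genes had a mean of at least 1 CPM over the 15 libraries without sperm, so recovery at lower levels was not tested. Each gene had the same spread in all groups and no library was made to stand apart, so noisier groups such as the eggs were not imitated. Between 12 h zygotes and eggs 8912 real genes were called, so the adjustment was stricter in the simulation and recovery may differ in the real data. For 12 h zygotes and eggs, edgeR recovered 2% of 50 genes changed 2-fold, 34% at 4-fold, 62% at 8-fold and 78% at 16-fold, and called 0 unchanged genes among 23069 in that step, where voom called 0 and DESeq2 71. For 24 h and 12 h zygotes it recovered 2%, 38%, 70% and 74%, and called 7 unchanged genes among 23049, where voom called 2 and DESeq2 97. For apical and basal cells it recovered 2%, 28%, 64% and 78%, and called 3 unchanged genes among 23057, where voom called 1 and DESeq2 60. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.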

Results

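The 18 libraries followed maize reproduction from the separate gametes through the zygote to the daughter cells of its first division, with 3 libraries for each of 6 groups. Total counts per library were 19083613 to 25000878 in sperm, 11761976 to 18373932 in egg, 11128444 to 18219740 in 12 h zygotes, 18159143 to 19449909 in 24 h zygotes, 19822868 to 25771168 in apical cells and 18199750 to 20313104 in basal cells. At least 1 CPM in all 3 libraries was reached by 12883 genes in sperm, 14129 in egg, 17019 in 12 h zygotes, 16986 in 24 h zygotes, 16301 in apical cells and 16432 in basal cells. The TMM factors ran from 0.454 to 0.502 in sperm and from 1.44 to 1.56 in 12 h zygotes.

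Sperm stood apart from every other group on the first principal component, which held 56.1% of the variance. Across genes, which are not independent replicates, Spearman correlations were 0.939 to 0.943 between sperm libraries, 0.479 to 0.576 between sperm and egg, and 0.910 to 0.927 between 12 h and 24 h zygotes. Apical and basal libraries correlated at 0.933 to 0.965 with each other, a range that contains the 0.938 to 0.964 between apical libraries. Eggs varied most, at 0.843 to 0.942, and both low values involved egg replicate 1. On the second component eggs lay apart from all other groups, and on the third the daughter cells, which overlapped each other, lay apart from zygotes and eggs.

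**Figure D1:**
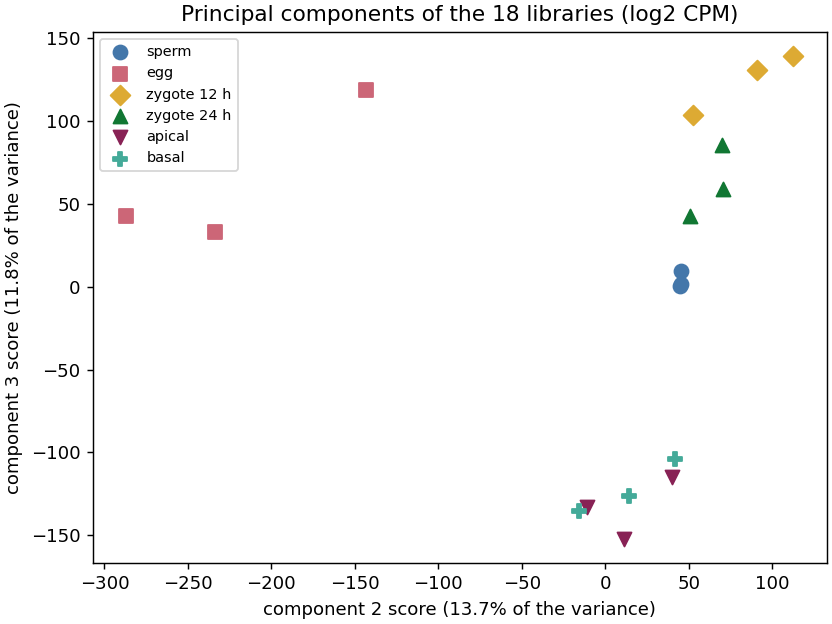
Scores of the 18 libraries on the second (x axis, 13.7% of the variance) and the third (y axis, 11.8%) principal component of log2 CPM, with 1 point per library and 1 colour and marker per group. Eggs sit at −287 to −144 on the second component, zygotes at positive scores on both, and apical and basal cells together at negative scores on the third.

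The scaling of libraries sets where fold changes are centred. With TMM, the median log2 fold change of all tested genes was −0.80 in sperm relative to egg, 0.06 in 12 h zygotes relative to egg, −0.13 in apical and −0.20 in basal cells relative to 24 h zygotes. With library size only these medians were −1.80, 0.58, −0.55 and −0.55. RLE scaling gave −0.47, 0.17, −0.15 and −0.20, and upper-quartile scaling −0.31, 0.18, −0.26 and −0.24. In 24 h relative to 12 h zygotes the median was −0.05 with TMM and −0.16 with library size only. The list test compares each list with the other genes, so its result is relative to these medians. Of 269 results for named genes, 0 changed direction under any alternative. These genes were chosen in the same data as called genes whose groups do not overlap, so that number was nearly fixed in advance.

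Sperm and egg were compared to describe which transcripts each gamete holds before fusion. RNRS3 (GRMZM2G323679), by its symbol a small subunit of ribonucleotide reductase, reached 121 ± 38.9 CPM in sperm (SD, n = 3) and had 0 counts in eggs, at least 1720-fold higher. Yucca3 (GRMZM2G107761), named after the flavin monooxygenases of auxin synthesis, stood at 69.9 ± 11.1 CPM in sperm against 0 counts in eggs, at least 1005-fold higher. The aquaporin gene por2 (GRMZM2G125023) was at 591 ± 46.2 CPM in sperm with 1 to 3 counts in eggs, a ratio of 13126 with a counting interval of 3633 to 108390. The cellulose synthase gene CesA-2 (GRMZM2G027723) was at 1950 ± 248 CPM in sperm and 20.1 ± 7.29 CPM in eggs. The cyclin gene cyclin9 (GRMZM2G017081) was at 509 ± 63.7 and 22.4 ± 1.90 CPM, and wox13A (GRMZM2G069274), a homeobox gene whose reference entry other IDs share, was at 276 ± 5.70 and 2.94 ± 0.778 CPM. On the egg side, the glycolytic gene GAPC2 (GRMZM2G180625) was at 4154 ± 1975 CPM in eggs and 9.42 ± 2.54 CPM in sperm, and rps27 (GRMZM2G066222), a ribosomal protein gene, at 893 ± 120 and 3.53 ± 1.01 CPM. The shugoshin gene sgo1 (GRMZM2G074082), whose products protect centromeric cohesion, had 0 counts in sperm and 64.3 ± 28.6 CPM in eggs, at least 716-fold lower in sperm. The embryo sac gene es1 (GRMZM2G012012) was at 810 ± 633 CPM in eggs and 1.28 ± 0.873 CPM in sperm.

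By edgeR, 15876 of 24835 tested genes differed between the gametes, 6123 higher and 9753 lower in sperm, and these genes passed at adjusted p = 1.36e-09 for RNRS3, 1.49e-11 for rps27 and 1.71e-07 for es1. With library size only, 4202 were higher and 12084 lower, so that the higher share went from 38.6% to 25.8%. Without egg replicate 1, which stood apart from the other eggs, 15579 genes were called. The log2 fold change of es1 was −9.25 ± 0.92, and it was −8.38 without egg replicate 1 and −9.90 without sperm replicate 2. For hap2 (GRMZM2G412911), at 771 ± 176 CPM in sperm and 5.35 ± 3.06 CPM in eggs, it was 7.17 ± 0.70, and 7.79 without egg replicate 1.

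Among the lists, all 10 tested genes of mature pollen were higher in sperm (camera, adjusted p = 0.00390, and adjusted p = 0.634 with an estimated correlation), with the profilin gene prf2 (GRMZM2G109842) at 89.0 ± 4.62 CPM in sperm and 1.21 ± 0.198 CPM in eggs. No group in the design separates RNA of the sperm cells from RNA of other pollen cells in the same preparation. Of 11 histone genes, 8 were higher in sperm, 1 lower and 2 did not pass (camera, adjusted p = 0.0118, and adjusted p = 0.634 with an estimated correlation). Of 15 DNA replication genes, 9 were higher, 2 lower and 4 did not pass (camera, adjusted p = 0.0118, and adjusted p = 0.634 with an estimated correlation). The helicase subunit gene MCM6 (GRMZM2G021069) was at 834 ± 24.8 CPM in sperm and 41.2 ± 35.3 CPM in eggs, a log2 fold change of 4.34 ± 0.61 that became 5.23 without egg replicate 2. Of 35 ribosomal protein genes, 25 were lower in sperm, 4 higher and 6 did not pass (camera, adjusted p = 0.00199, and adjusted p = 0.634 with an estimated correlation). All 5 egg and embryo sac genes were lower in sperm (camera, adjusted p = 0.0259, but 0.0623 with library size only, and adjusted p = 0.634 with an estimated correlation). Of 19 tubulin and kinesin genes, 12 were higher, 1 lower and 6 did not pass (camera, adjusted p = 0.0193, and adjusted p = 0.634 with an estimated correlation), whereas with library size only 7 were higher and 5 lower and the list no longer passed (camera, adjusted p = 0.0655). Of 14 heat shock genes, 11 were lower in sperm, also 11 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0566).

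Zygotes at 12 h were compared with eggs to ask which transcripts change soon after fertilization. RNRS3, with 0 counts in eggs, reached 86.0 ± 26.3 CPM at 12 h, at least 1072-fold higher, and Yucca3 reached 25.6 ± 10.3 CPM, at least 337-fold higher. The annexin gene Ann9 (GRMZM2G132461) and the WUSCHEL-related homeobox gene wox9A (GRMZM2G133972) also had 0 counts in eggs, and reached 28.9 ± 7.01 CPM and 12.1 ± 2.02 CPM at 12 h, at least 363-fold and 152-fold higher. ABP1 (GRMZM2G117603), which the reference also lists as the actin-depolymerizing factor gene adf1, went from 0.703 ± 0.171 to 257 ± 42.7 CPM, and TIFY27 (GRMZM2G089736), of the family of jasmonate repressors, from 1.87 ± 1.62 to 95.8 ± 13.2 CPM. The replication helicase gene MCM7 (GRMZM2G065205) went from 13.6 ± 9.20 to 329 ± 15.6 CPM. In the other direction, the enolase gene eno2 (GRMZM2G048371) fell from 2277 ± 986 to 565 ± 75.8 CPM, the histone deacetylase gene Hda1 (GRMZM2G457889) from 279 ± 46.2 to 80.6 ± 33.4 CPM, and ADPRT-1 (GRMZM5G831712), by its symbol an ADP-ribosyltransferase, from 189 ± 2.54 to 64.9 ± 13.3 CPM.

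By edgeR, 8912 of 23806 tested genes differed, 4613 higher and 4299 lower at 12 h, with adjusted p = 5.03e-07 for RNRS3, 7.34e-05 for MCM7 and 0.000293 for Hda1. With library size only, 6142 were higher and 2174 lower, and the higher share went from 51.8% to 73.9%. The fit of only the 2 groups called 3785 genes, and 11999 were called without egg replicate 1. Without egg replicate 2, the log2 fold change of MCM7 was 5.28 in place of 4.59 ± 0.54, and that of eno2 was −1.42 in place of −2.01 ± 0.30.

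**Figure D2:**
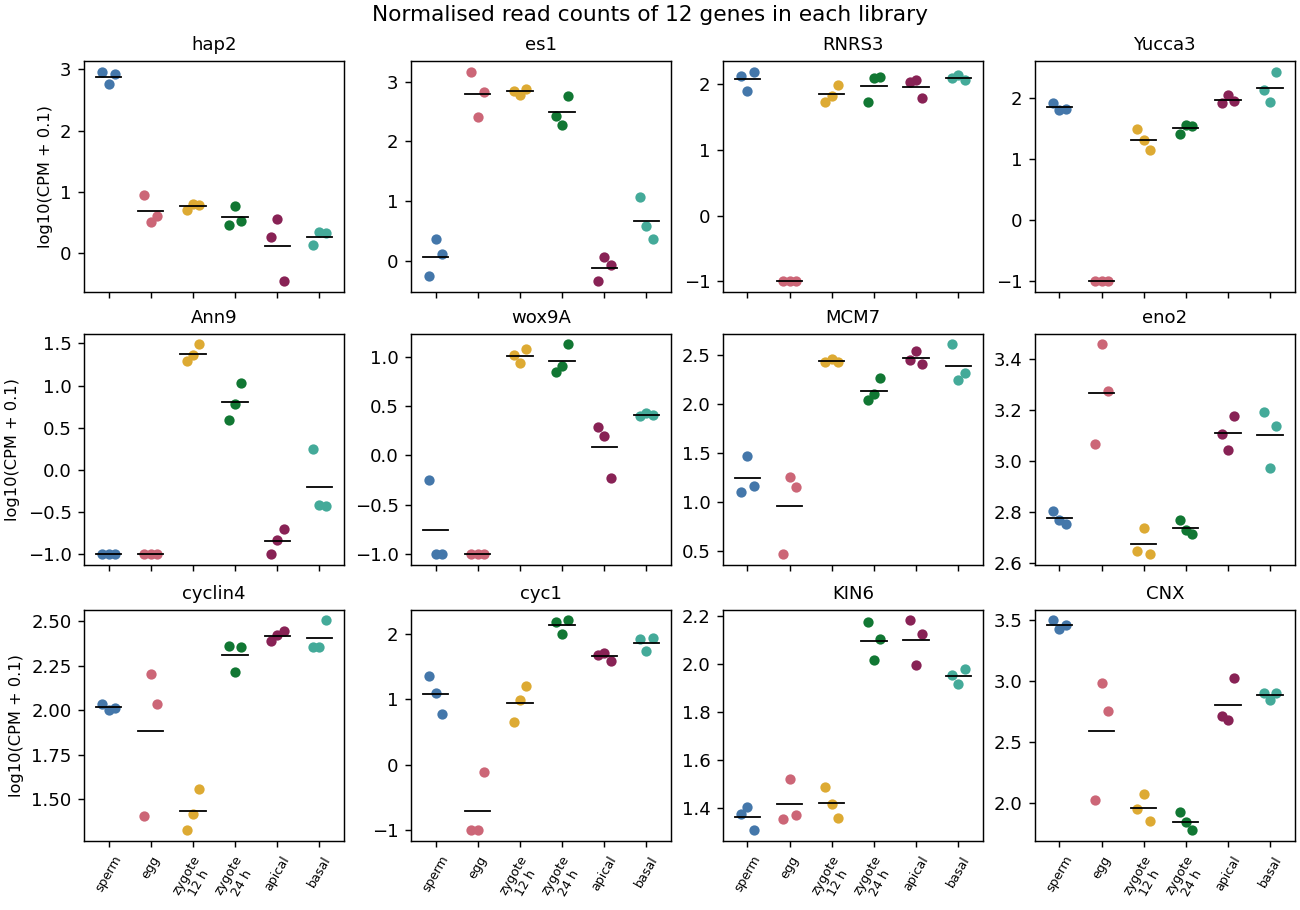
Normalised read counts of 12 named genes, as log10(CPM + 0.1) on the y axis, in the 6 groups on the x axis, with 1 dot per library and a line at the mean of the 3 log values. RNRS3, Yucca3, Ann9 and wox9A had 0 counts in eggs and were detected at 12 h, whereas cyc1 and KIN6 were higher at 24 h than at 12 h.

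Several transcription factor families ranked above the other genes at 12 h with the preset correlation, and none with an estimated one. Of 28 AP2/EREB factors, 17 rose, 1 fell and 10 did not pass (camera, adjusted p = 1.58e-05, and adjusted p = 0.221 with an estimated correlation). EREB139 (GRMZM2G103085) went from 1 to 3 counts in all eggs to 49.4 ± 30.7 CPM, a ratio of 578 with a counting interval of 198 to 2804, and its fitted log2 fold change of 9.22 became 12.84 without egg replicate 3. Of 34 WOX, HD-ZIP IV, KNOX and related patterning factors, 16 rose, 2 fell and 16 did not pass (camera, adjusted p = 6.74e-05, and adjusted p = 0.163 with an estimated correlation). In the list of embryo patterning factors fixed beforehand, 4 of 7 rose, 5 adjusted over the list alone, and 0 fell (camera, adjusted p = 0.00248, and adjusted p = 0.249 with an estimated correlation). Of 34 MYB factors 14 rose and 0 fell, of 22 bHLH factors 10 rose and 0 fell, and of 23 bZIP factors 9 rose and 1 fell (camera, adjusted p = 0.00427, 0.00664 and 0.00546, and adjusted p = 0.249, 0.221 and 0.196 with an estimated correlation). Of 34 MADS-box factors, 11 rose and 2 fell (camera, adjusted p = 0.0356, and adjusted p = 0.511 with an estimated correlation). The MADS-box call was lost with library size only (camera, adjusted p = 0.0508) and without egg replicate 1 (camera, adjusted p = 0.103). Examples were bZIP46 (GRMZM2G037910), with 0 counts in eggs and 13.2 ± 4.52 CPM at 12 h, at least 161-fold higher, and bHLH168 (GRMZM2G030744), which went from 15.1 ± 6.76 to 73.2 ± 17.5 CPM.

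Of 55 genes of jasmonate, WRKY and pathogenesis responses, 32 were higher, 4 lower and 19 did not pass (camera, adjusted p = 1.58e-05, and adjusted p = 0.249 with an estimated correlation). In the wounding and defence list fixed beforehand, which shares members with it, 21 of 36 rose and 3 fell, 23 and 4 adjusted over the list alone (camera, adjusted p = 0.000587, and adjusted p = 0.251 with an estimated correlation). The oxophytodienoate reductase gene opr6 (GRMZM2G068947) had 0 counts in eggs and 10.02 ± 6.89 CPM at 12 h, at least 122-fold higher, and its fitted log2 fold change, no bound for such a gene, went from 10.50 to 9.88 without zygote 12 h replicate 1. Of 40 auxin genes, 17 rose and 0 fell (camera, adjusted p = 0.00206, and adjusted p = 0.156 with an estimated correlation). Of 38 cell wall genes, 19 rose and 2 fell (camera, adjusted p = 0.00233, and adjusted p = 0.156 with an estimated correlation), with the expansin gene expB2 (GRMZM2G021621) going from 2.20 ± 1.37 to 70.9 ± 12.7 CPM, a log2 fold change of 5.01 that was 5.63 without egg replicate 1. Of 7 aquaporin genes, 3 rose and 0 fell (camera, adjusted p = 0.00215, and adjusted p = 0.221 with an estimated correlation). The protocol released these cells from ovules, and the eggs were isolated cells too, so an effect of isolation that both share would cancel. No group in the design separates an effect of isolation that differs between zygotes and eggs from that of fertilization.

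Of 15 DNA replication genes, 8 rose, 2 fell and 5 did not pass (camera, adjusted p = 0.00814, and adjusted p = 0.249 with an estimated correlation). Of 11 histone genes, 6 rose, 1 fell and 4 did not pass (camera, adjusted p = 0.0112, and adjusted p = 0.386 with an estimated correlation). The histone H4 gene H4C13 (GRMZM2G149178), whose reference entry other IDs share, went from 4.93 ± 4.29 to 275 ± 134 CPM, a log2 fold change of 5.79 that was 6.46 without egg replicate 3. The 23 cell cycle genes were divided, with 8 higher, 10 lower and 5 that did not pass (camera, adjusted p = 0.842).

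Of 35 ribosomal protein genes, 20 fell and 0 rose (camera, adjusted p = 0.000587, and adjusted p = 0.249 with an estimated correlation), although 8 fell and 1 rose with library size only. Of 13 translation initiation and elongation factors, 8 fell and 0 rose (camera, adjusted p = 0.00427, and adjusted p = 0.292 with an estimated correlation), with 6 lower and 2 higher with library size only. The elongation factor gene elfa7 (GRMZM2G110509) went from 1063 ± 645 to 210 ± 44.1 CPM, a log2 fold change of −2.34 ± 0.40 that was −1.63 without egg replicate 2. Of 84 genes of chromatin modifiers and small RNA pathways, 33 fell, 7 rose and 44 did not pass (camera, adjusted p = 0.00206, and adjusted p = 0.258 with an estimated correlation), but 20 fell and 20 rose with library size only, where the list still ranked below the other genes (camera, adjusted p = 0.00624). Of 13 autophagy genes, 7 fell and 0 rose (camera, adjusted p = 0.00779, and adjusted p = 0.249 with an estimated correlation). Of 18 genes of meiotic recombination and repair, 8 fell and 4 rose, against 5 and 5 with library size only (camera, adjusted p = 0.0380, and adjusted p = 0.329 with an estimated correlation). That call was lost without egg replicate 1 (camera, adjusted p = 0.0598).

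To describe transcripts that appear after fertilization, genes detected at 12 h in neither gamete were counted: 282 genes met these limits, 19 of them named. Among named genes the highest at 12 h were Myb36 (GRMZM2G056407) at 45.8 ± 60.6 CPM, Ann9 at 24.3 ± 5.82 CPM, the lipoxygenase gene lox1 (GRMZM2G156861) at 19.9 ± 24.9 CPM and OBF1 at 18.3 ± 7.02 CPM. Myb56 followed at 15.1 ± 4.10 CPM. The spread between libraries exceeded the mean for Myb36 and lox1, whose fitted log2 fold changes over egg went from 12.94 to 10.88 without zygote 12 h replicate 3 and from 11.74 to 9.86 without zygote 12 h replicate 2. GRMZM2G328205, singled out after its values were seen and without a name in the reference, had 0 counts in both gametes and 259 ± 64.7 CPM at 12 h, 452 ± 71.8 CPM at 24 h, 335 ± 91.2 CPM in apical and 425 ± 25.6 CPM in basal cells. The number of genes was 477 without egg replicate 1 and 451 without zygote 12 h replicate 2. With library size only it was 449, with a minimum of 2 CPM at 12 h it was 149, and with absence taken as under 0.5 CPM it was 668.

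A further 57 genes, 8 of them named, were detected in sperm and at 12 h but not in egg. RNRS3 was at 122 ± 39.2 CPM in sperm and 72.3 ± 21.9 CPM at 12 h, and Yucca3 at 70.7 ± 10.6 and 21.6 ± 8.73 CPM. The kinase gene cipk31 was at 14.8 ± 5.40 CPM at 12 h against 2.58 CPM in sperm, MADS11 at 10.3 ± 9.61 against 1.41 CPM, and opr6 at 8.44 ± 5.83 against 6.08 CPM. The count was 108 without egg replicate 1 and 122 without egg replicate 3. It was 33 with a minimum of 2 CPM, 35 with 0 counts as absence and 136 with under 0.5 CPM as absence. Also chosen after its values were seen, por2, one of the 57 genes, was at 598 ± 50.8 CPM in sperm and 2.45 ± 1.18 CPM at 12 h. PepR1, chosen in the same way, was at 6129 ± 1352 and 63.6 ± 8.43 CPM, but at 1.69 ± 1.76 CPM in eggs it was not among the 57.

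Zygotes at 24 h were compared with those at 12 h to follow development before the first division. The cyclin genes cyc1 (GRMZM2G034647) and cyc3 (GRMZM2G073671) went from 11.9 ± 6.88 to 162 ± 39.0 CPM and from 4.15 ± 5.10 to 161 ± 49.3 CPM. The kinesin genes KIN6 (GRMZM2G114861), KIN13 (GRMZM2G034828) and kin11 (GRMZM2G436981), motors that move along microtubules, went from 31.6 ± 4.63 to 150 ± 27.7 CPM, from 2.84 ± 1.31 to 77.3 ± 18.1 CPM and from 2.82 ± 0.849 to 64.1 ± 20.4 CPM. CSLD1 (GRMZM2G015886), a cellulose synthase-like gene, went from 1.62 ± 0.658 to 172 ± 96.2 CPM. NTGP5 (GRMZM2G025470) was the only called gene with an informative name that fell, from 158 ± 26.3 to 49.5 ± 9.48 CPM.

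By edgeR, 248 of 23806 genes differed, 239 higher and 9 lower at 24 h, with adjusted p = 2.79e-05 for CSLD1, 0.000243 for KIN6 and 0.00716 for cyc1. DESeq2 called 736, 572 higher and 164 lower, voom 1573, 903 higher and 670 lower, and the fit of only the 2 groups 890, 662 higher and 228 lower, so that the higher share was 96.4% with edgeR, 77.7% with DESeq2, 57.4% with voom and 74.4% in that fit. In the simulation of this comparison, edgeR called 7 unchanged genes, voom 2 and DESeq2 97. Since every simulated group had the same spread, these numbers do not show which tool is nearer the truth in the real libraries. The number was 127 without zygote 12 h replicate 1, 159 without zygote 12 h replicate 3, 141 without zygote 24 h replicate 1 and 165 without zygote 24 h replicate 3. The call of cyc1 was lost without zygote 12 h replicate 1 (edgeR, adjusted p = 0.0533), and that of NTGP5 without zygote 12 h replicate 3 (edgeR, adjusted p = 0.0644), zygote 24 h replicate 1 (0.0738) or zygote 24 h replicate 3 (0.0823). The log2 fold change of cyc3 was 7.06 without zygote 12 h replicate 3, in place of 5.31 ± 0.78.

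Of 19 tubulin and kinesin genes, 7 rose, 0 fell and 12 did not pass (camera, adjusted p = 1.60e-08, and adjusted p = 0.230 with an estimated correlation). Of 23 cell cycle genes, 6 rose, 0 fell and 17 did not pass (camera, adjusted p = 5.04e-06, and adjusted p = 0.0599 with an estimated correlation). The 11 histone genes ranked higher as a list (camera, adjusted p = 0.00456, and adjusted p = 0.556 with an estimated correlation), although 0 passed singly by edgeR. The 84 chromatin genes also ranked higher, with 1 called, sdg118, whose log2 fold change of 3.29 was 4.07 without zygote 12 h replicate 3 (camera, adjusted p = 0.00279, and adjusted p = 0.556 with an estimated correlation). Aquaporin genes and patterning factors ranked lower with 0 members called by edgeR (camera, adjusted p = 0.0277 and 0.0352, and adjusted p = 0.556 for both with an estimated correlation), and the latter did not pass without egg replicate 1 (camera, adjusted p = 0.0595).

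Genes whose level at 12 h stood apart on both sides were counted next. By edgeR 5 genes rose from egg to 12 h and fell by 24 h, of which NTGP5 has a name, at 27.5 ± 9.60 CPM in eggs, 158 ± 26.3 CPM at 12 h and 49.5 ± 9.48 CPM at 24 h. The reverse, a fall and then a rise, was found for 56 genes. The balance depended on the tool: DESeq2 gave 88 genes that rose and fell and 197 of the reverse, voom 434 and 277, and fits of only the 2 groups 108 and 91. Examples, chosen after their values were seen, were cyclin4, at 113 ± 78.4, 32.9 ± 9.02 and 243 ± 44.1 CPM, the checkpoint gene mad2, at 162 ± 33.8, 85.0 ± 24.8 and 305 ± 52.6 CPM, and the centromere gene CenpcA, at 58.9 ± 13.2, 28.1 ± 3.46 and 73.7 ± 16.2 CPM. Both comparisons use the 12 h libraries. Of all tested genes, 63.9% had fold changes of opposite sign in the 2 comparisons, against a mean of 66.6% in 20 simulations of unchanged groups that share the 12 h libraries. In these simulations, which give few calls by construction, 0 genes followed either course by edgeR, and independent lists would share 1.74 and 43.2 genes. The number that rose and fell was 32 without egg replicate 1, 9 without egg replicate 2, 1 without zygote 12 h replicate 1, 2 without zygote 12 h replicate 2 and 0 without zygote 12 h replicate 3. It was 0, 1 and 0 without zygote 24 h replicates 1, 2 and 3. The number of the reverse course was 200 without egg replicate 1, 23 and 33 without zygote 12 h replicates 1 and 3, 30 without zygote 24 h replicate 1 and 26 with library size only.

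**Figure D3:**
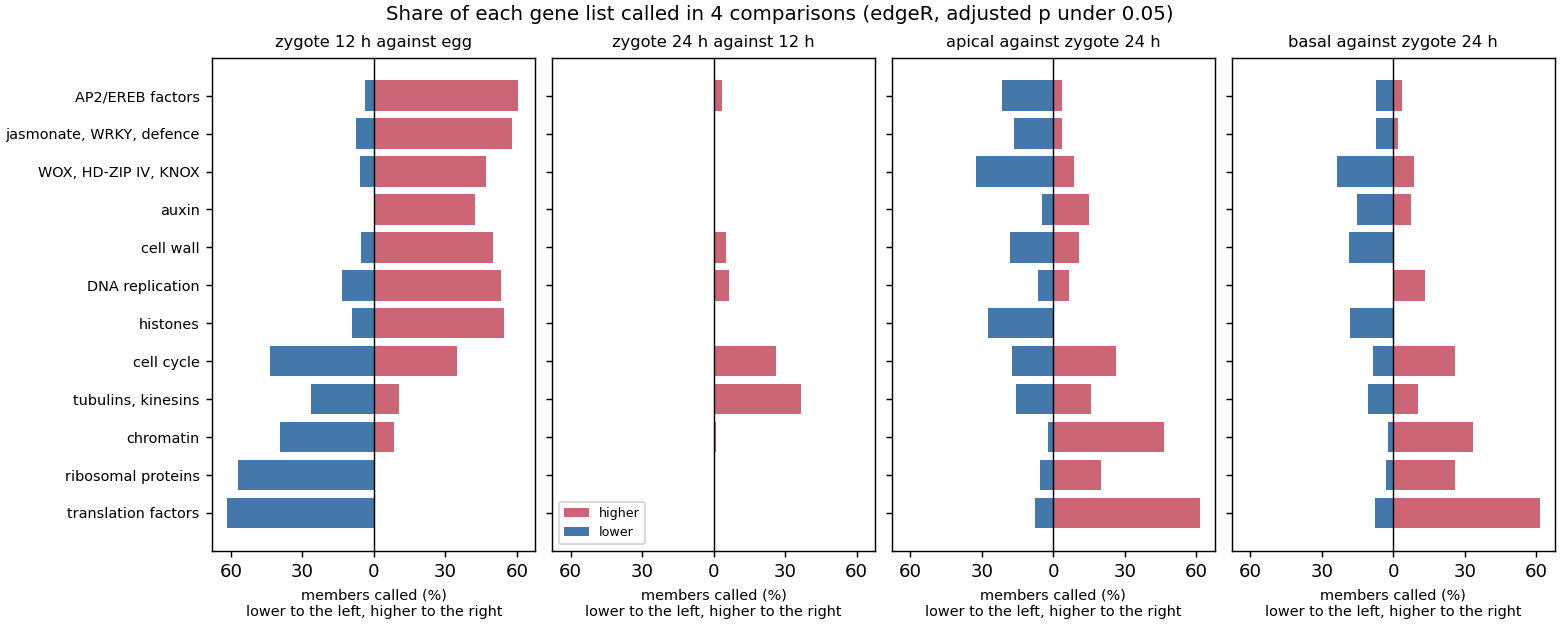
Share of the tested members of 12 gene lists (y axis) that edgeR called higher (bars to the right, %) or lower (bars to the left, %) in 4 comparisons, each an own panel. At 12 h, 17 of 28 AP2/EREB factors were higher (19 with library size only), 20 of 35 ribosomal protein genes lower and 0 higher (8 and 1 with library size only) and 33 of 84 chromatin genes lower and 7 higher (20 and 20 with library size only), while 39 chromatin genes were higher in apical and 28 in basal cells (25 and 23 with library size only).

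Apical and basal cells were each compared with 24 h zygotes to ask what changes across the first division. The Dicer gene dcl1 (GRMZM2G040762) was at 194 ± 55.0 CPM in apical cells and 46.4 ± 5.51 CPM in 24 h zygotes, and chr124, an SNF2-type remodeller gene counted under more than 1 ID (here GRMZM2G435541), at 42.6 ± 12.7 and 0.509 ± 0.378 CPM. The endoplasmic reticulum chaperone gene CNX (GRMZM2G022180), by its symbol a calnexin, was at 777 ± 367 CPM in apical and 868 ± 59.2 CPM in basal cells against 83.2 ± 14.9 CPM. The auxin response factor gene ARF1 (GRMZM2G169820) was at 73.5 ± 13.1 CPM in apical cells and 10.01 ± 2.82 CPM in zygotes, and the starch synthase gene ss2 (GRMZM2G152908) at 964 ± 237 CPM in basal cells and 114 ± 39.99 CPM in zygotes. The embryo sac genes es1, es2 (GRMZM2G128301) and es4 (GRMZM2G009359) fell from 405 ± 241, 387 ± 181 and 391 ± 187 CPM in zygotes to 0.838 ± 0.413, 18.2 ± 3.36 and 10.4 ± 0.786 CPM in apical cells. Also lower was the HD-ZIP IV gene HDZIV14_OCL14 (GRMZM2G145690), at 11.5 ± 2.24 CPM in zygotes, 0.748 ± 0.190 CPM in apical and 0.622 ± 0.311 CPM in basal cells. ZCN11 (GRMZM2G117057), at 15.5 ± 7.44 CPM in zygotes, had 0 counts in apical cells, at least 300-fold lower. The annexin gene Ann6 (GRMZM2G061950) fell from 388 ± 156 to 31.9 ± 7.23 CPM in basal cells, and es1 to 6.69 ± 5.71 CPM.

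By edgeR, 5916 of 23806 genes differed in apical cells, 3101 higher and 2815 lower, and 4276 in basal cells, 2335 higher and 1941 lower. Adjusted p was 0.000404 for dcl1 and 0.00202 for CNX in apical cells, and 0.00240 for CNX and 7.50e-05 for Ann6 in basal cells. With library size only, 1825 were higher and 4337 lower in apical cells (29.6% higher, against 52.4%), and 1497 higher and 3018 lower in basal cells (33.2%, against 54.6%). With upper-quartile scaling, 2653 were higher and 3257 lower in apical cells. The apical count was 3391 and 2713 without zygote 24 h replicates 2 and 3, and 2721 without apical replicate 3, and voom called 10212. The basal count was 2460, 2031 and 1690 without zygote 24 h replicates 1, 2 and 3, and 1882, 2808 and 1998 without basal replicates 1, 2 and 3, while voom called 10119 and the fit of only the 2 groups 8194. The log2 fold change of es1 was −8.92 ± 0.90 in apical cells, −8.32 without zygote 24 h replicate 3. In basal cells it was −5.92 ± 0.77, −5.32 without zygote 24 h replicate 3 and −6.91 without basal replicate 1.

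Of the 84 chromatin genes, 39 rose in apical cells, 2 fell and 43 did not pass (camera, adjusted p = 2.37e-08, and adjusted p = 0.533 with an estimated correlation). In basal cells 28 rose, 2 fell and 54 did not pass (camera, adjusted p = 5.71e-07, and adjusted p = 0.553 with an estimated correlation). Both list calls held with library size only, where 25 and 23 rose. Of 13 translation factors, 8 rose and 1 fell in each cell (camera, adjusted p = 0.0666 and 0.0503), with eIF-5 (GRMZM2G165917) at 1295 ± 338 CPM in apical cells and 282 ± 24.3 CPM in zygotes. The elongation factor gene elfa3 (GRMZM2G154218) was at 1198 ± 231 CPM in basal cells and 323 ± 25.3 CPM in zygotes. In basal cells, 9 of 35 ribosomal protein genes rose and 1 fell (camera, adjusted p = 0.0361, and adjusted p = 0.553 with an estimated correlation), a call lost with library size only, where the median of the list turned negative (camera, adjusted p = 0.108). Also in basal cells, 5 of 21 endoplasmic reticulum folding genes rose and 1 fell, and 8 of 34 patterning factors fell and 3 rose (camera, adjusted p = 0.0361 for each, and adjusted p = 0.553 for both with an estimated correlation). Of 55 jasmonate and defence genes 4 fell and 1 rose, and of 22 bHLH factors 2 fell and 0 rose (camera, adjusted p = 0.0187 and 0.0399, and adjusted p = 0.553 for both with an estimated correlation). None of these 4 lists passed with library size only. Of the egg marker list fixed beforehand, too small for a list test, 3 of 3 tested genes fell in each cell by edgeR, also 3 adjusted over the list alone. In apical cells 5 of the 10 pollen genes were called higher by edgeR, with levels that came from apical replicate 1, where PG14 (GRMZM2G418644), chosen after its values were seen, was at 68.6 CPM against 0 and 0.0970 CPM in apical replicates 2 and 3, and the list did not pass (camera, adjusted p = 0.316).

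Apical and basal cells were compared with each other to ask whether the sister cells differ. By edgeR, 0 of 23806 genes passed, with 1267 at an unadjusted p under 0.05 and a smallest adjusted p of 0.377, whereas DESeq2 called 75, voom 9 and the fit of only the 2 groups 2. These fits took the libraries as unpaired. Correlations of the deviations of same-numbered apical and basal libraries were 0.27316, 0.30011 and −0.000467, which does not exclude pairing. A test that pairs these cells alone was not run, so the 0 calls do not settle whether the sister cells differ. In the simulation of this comparison, the changed genes had a mean of at least 1 CPM. Of these, edgeR recovered 28% of those changed 4-fold and 64% of those changed 8-fold, and it called 3 unchanged genes. DESeq2 recovered 60% and 82% and called 60 unchanged genes. Among genes chosen after their values were seen, the embryo sac gene es4 was at 10.4 ± 0.786 CPM in apical and 57.5 ± 10.5 CPM in basal cells (log2 −2.47 ± 0.54, edgeR adjusted p = 0.550), and es2 at 18.2 ± 3.36 and 72.9 ± 15.9 CPM (edgeR, adjusted p = 0.778). In the egg marker list fixed beforehand, 3 of 3 genes passed as lower in apical cells when adjusted over the list alone, and 0 over all genes by edgeR.

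As lists, auxin genes and MADS-box factors ranked higher in apical than in basal cells (camera, adjusted p = 0.000683 for each, and adjusted p = 0.132 and 0.979 with an estimated correlation). Egg and embryo sac genes ranked lower, as did ribosomal protein genes (camera, adjusted p = 0.00185 and 0.0416, and adjusted p = 0.979 for both with an estimated correlation). Pollen genes ranked higher (camera, adjusted p = 0.00836, and adjusted p = 0.979 with an estimated correlation), but without apical replicate 1 they ranked lower and did not pass (camera, adjusted p = 0.4997). By edgeR, 0 members of these 5 lists were called. The list tests also took apical and basal libraries as unpaired.

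**Figure D4:**
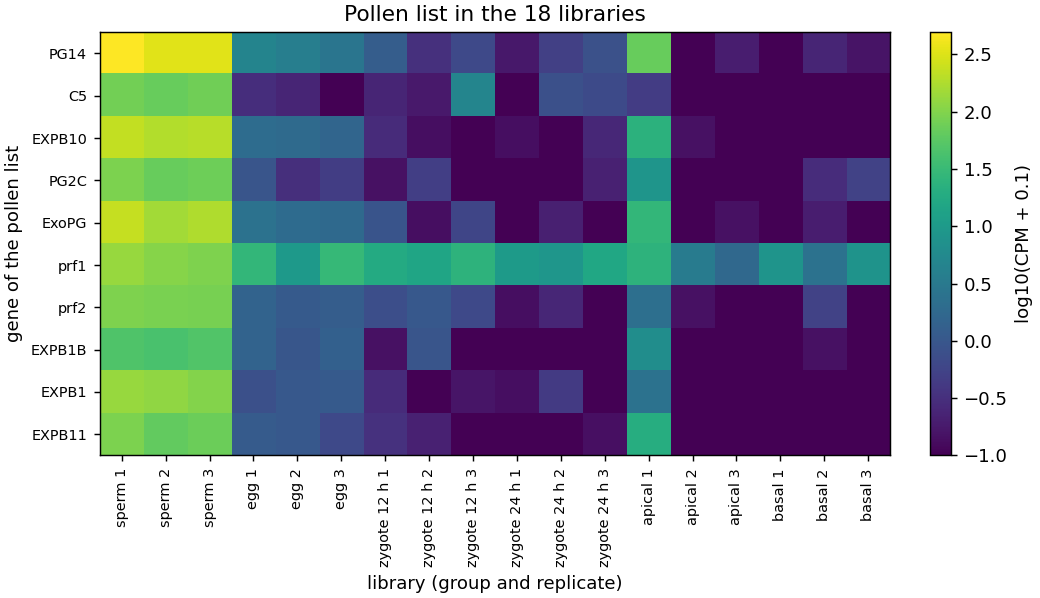
Heat map of log10(CPM + 0.1) of the 10 genes of the pollen list (y axis) in each of the 18 libraries (x axis), where lighter colours stand for higher values. All 10 are highest in the 3 sperm libraries, and most are higher in apical replicate 1, where PG14 is at 68.6 CPM, than in apical replicates 2 and 3.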

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

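The tests of sperm RNA and the list tests without apical replicate 1 were chosen only after the results were seen.

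In the direct comparison of apical with basal cells, 5 lists differed with camera and its preset correlation, and 0 of the 5 calls held with an estimated one. These are the same tests as in the Results, not further ones. They took the libraries as unpaired, and a test that pairs apical with basal cells alone was not run. With fry, 0 lists passed in this comparison. Auxin genes (adjusted p = 0.000683) and MADS-box factors (adjusted p = 0.000683) ranked higher in apical cells by camera (adjusted p = 0.132 and 0.979 with an estimated correlation), and without apical replicate 1 both still did (adjusted p = 9.35e-05 and 1.44e-06). Egg and embryo sac genes (adjusted p = 0.00185) and ribosomal protein genes (adjusted p = 0.0416) ranked lower by camera (adjusted p = 0.979 for both with an estimated correlation), also without apical replicate 1 (adjusted p = 0.0308 and 0.00396). Pollen genes ranked higher by camera (adjusted p = 0.00836, and adjusted p = 0.979 with an estimated correlation), but lower and without passing when apical replicate 1 was left out (adjusted p = 0.4997). By edgeR 0 members of these lists passed over all genes, while DESeq2 called 75 genes in all and voom 9. Adjusted over each list alone, 6 pollen genes and 3 egg and embryo sac genes passed by edgeR. Of 23806 tested genes, 1267 were at an unadjusted p under 0.05, near the share of 0.05 passed without any difference. Of 10 splits of the 6 libraries, 5 called at least 5 lists and the highest other number was 10, and 10 splits are too few for a share under 0.05.

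Among the pollen genes in apical replicate 1, PG14 was at 68.6 CPM, against 0 and 0.0970 CPM in apical replicates 2 and 3, EXPB10 at 23.4, 0.0471 and 0 CPM, and ExoPG at 28.0, 0 and 0.0485 CPM. These genes were chosen after their values were seen, and others were lower in that library, down to C5 at 0.359 CPM. All 10 genes of the list were also present in the sperm libraries. If RNA or index reads of the sperm libraries had entered the library, other sperm genes could reach a like share of their sperm level, but 7 of the 10 most abundant stayed under 0.1 of the level needed beyond their counting error (0.0797 against 345 CPM for the most abundant), while the 3 others were at 12.9 to 16.8 CPM where 33.0 to 52.4 CPM were needed. The median share was 0.431% over 74 sperm genes and 11.5% over 7 pollen genes, a ratio of 0.0375 with an interval of 0.00346 to 0.330. The 7 genes argue against the sperm libraries as the whole source, but by a limit, more than 5 of 10 genes, that was set after they had been counted: the first rule, a ratio under 0.1 without its interval, also went against it, whereas under the later ones, the quartiles of the genes, the interval of the ratio and then 8 of 10 genes, all set after results were seen, the explanation had stayed open. Pollen RNA from elsewhere was not tested and stays open, and no biological explanation was tested.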

How the results depend on the processing

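The list tests without egg replicate 1 and without apical replicate 1 were chosen only after the results were seen. Of 269 results for named genes, 203 kept their direction and stayed past the threshold under every alternative run. That 0 changed direction was nearly fixed in advance, since these genes were chosen as called genes whose groups do not overlap. In all, 50 were no longer past an adjusted p of 0.01 and 15 were lost with library size only. When a library was left out, only the comparisons that hold it were rerun. Without zygote 24 h replicates 1, 2 and 3, 25, 27 and 41 results were lost, and 111, 109 and 95 were kept. Where a count moved, the cause was not tested, except that the limit of 0.01 keeps fewer genes by construction. Fits with 1 library less hold fewer samples, where the spread is shared with the other groups. Fewer samples do not account for counts that rose, such as 8912 to 11999 in 12 h zygotes against eggs without egg replicate 1.

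By edgeR, 12 h zygotes against eggs gave 8912 genes, 4961 at an adjusted p under 0.01, 3785 with only the 2 groups and 6465 to 11999 without 1 library. For 24 h against 12 h zygotes, 248 genes by edgeR became 736 with DESeq2, 1573 with voom, 137 at an adjusted p under 0.01, 890 with only the 2 groups and 127 to 175 without 1 library. For apical cells against 24 h zygotes, 5916 became 10212 with voom, 2210 at an adjusted p under 0.01 and 2713 to 4302 without 1 library. For basal cells, 4276 became 10119 with voom, 1412 at an adjusted p under 0.01, 8194 with only the 2 groups and 1690 to 2808 without 1 library. Apical against basal cells gave 0 genes by edgeR, also without any 1 library, 75 with DESeq2, 9 with voom and 2 with only the 2 groups. By edgeR 1267 genes were at an unadjusted p under 0.05, near the share of 0.05 passed without any difference. Sperm against egg gave 14709 to 15669 without 1 library.

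The 5 genes that rose and then fell became 3 without a filter, 88 with DESeq2, 434 with voom, 0 at an adjusted p under 0.01 (edgeR), 108 with only the 2 groups and 0 to 32 without 1 library, and the 56 of the reverse course became 197 with DESeq2, 277 with voom, 91 with only the 2 groups, 21 at an adjusted p under 0.01 (edgeR), 26 with library size only and 23 to 200 without 1 library. Genes detected in neither gamete were 449 with library size only, 149 at 2 CPM or more, 668 with absence under 0.5 CPM and 293 to 477 without 1 library. Genes shared by sperm and 12 h zygotes were 33 at 2 CPM or more, 35 with 0 counts as absence, 136 under 0.5 CPM and 60 to 122 without 1 library. List calls were 43 with camera, 0 with an estimated correlation, 74 with fry, 38 with library size only, 50 without egg replicate 1 and 46 without apical replicate 1. The total of fry hides lost calls: it called 2 lists in 24 h against 12 h zygotes and 0 in apical against basal cells, where camera called 6 and 5. In basal cells against zygotes, jasmonate and defence genes and ribosomal protein genes did not pass with fry (adjusted p = 0.0506 and 0.0579). Pollen genes in apical against basal cells turned to the lower side without apical replicate 1 (camera, adjusted p = 0.4997, and 0.0239 on the higher side without egg replicate 1).

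The samples were taken as unpaired by a rule that all 3 correlations of same-numbered deviations be over 0.1, which no comparison met. Missing that rule does not exclude pairing in apical and basal cells, where the correlations were 0.27316, 0.30011 and −0.000467. In the 6 comparisons, 2, 1, 0, 1, 1 and 2 of 3 numbers correlated best with their own. With the replicate number as a block, edgeR called 15318, 7949, 187, 4895, 3375 and 0 genes in the 6 comparisons, 2 genes that rose and then fell, 283 and 57 detected genes and 43 lists. This block gave all groups of a fit the same replicate effect, and a test that pairs apical with basal cells alone was not run. Depth limits the genes with 0 counts, whose folds are bounds, and genes near 1 CPM.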

Other observations

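The tests of sperm RNA in eggs and of zygote RNA in egg replicate 1 were chosen only after the results were seen.

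Of 18 genes of glycolysis and sugar metabolism, 9 fell from egg to 12 h, 3 rose and 6 did not pass, and of 21 endoplasmic reticulum folding genes 9 fell, 1 rose and 11 did not pass, and neither list passed (camera, adjusted p = 0.0559 and 0.0807). Of 18 NAC factors, 6 rose, 2 fell and 10 did not pass (camera, adjusted p = 0.117). Of 6 photosynthesis genes tested at 12 h against eggs, 0 rose and 1 fell by edgeR (camera, adjusted p = 0.716). Their number depends on which genes the reference names, and this comparison does not show whether RNA of green tissue was in both groups.

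Levels of some named genes over all 6 groups, chosen after their values were seen, show how unlike the courses were. The annexin gene Ann6 was at 3.08 ± 1.27 CPM in sperm, 1389 ± 247 CPM in eggs, 534 ± 36.0 CPM at 12 h, 329 ± 132 CPM at 24 h, 32.8 ± 0.908 CPM in apical and 28.0 ± 6.11 CPM in basal cells. The elongation factor gene elfa7 was at 107 ± 20.2, 919 ± 557, 177 ± 36.9, 248 ± 23.9, 758 ± 169 and 703 ± 147 CPM in the same order. The checkpoint gene mad2 was at 2489 ± 380 CPM in sperm and 140 ± 31.1 CPM in eggs, and at 477 ± 199 and 585 ± 134 CPM in apical and basal cells.

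Pollen genes, picked here after their values were seen, were also counted in eggs, with C5 at 0 to 0.209 CPM, PG14 at 2.66 to 4.52 CPM and prf1, counted in all 18 libraries, at 9.90 to 30.1 CPM. RNA or index reads of the sperm libraries could account for this: 4 of the 10 most abundant other sperm genes were under 0.1 of the level needed, which was 2.88 to 32.2 CPM, beyond their counting error, and the others were not. The median share of the sperm level was 0.331% over 74 sperm genes and 1.07% over 7 pollen genes, a ratio of 0.309 with an interval of 0.223 to 0.732. These values do not decide, and no biological explanation was tested.

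Egg replicate 1 correlated at 0.843 and 0.854 with the other eggs, which correlated at 0.942 with each other, and at up to 0.859 with 12 h and 0.844 with 24 h zygotes, where the other eggs reached 0.790 and 0.803. Its lower depth is excluded as the whole cause, since the difference was 0.127 after the other eggs were thinned to its depth (0.926 against 0.799). Zygote RNA or a zygote label as the whole cause is excluded too, despite these correlations: over 174 zygote genes near 0 in the other eggs, the median share of the 12 h level was 0.00923, with an upper quartile of 0.0889. In this library 347 genes were at least 10-fold lower and 278 at least 10-fold higher than in the other eggs, 202 of the latter above every zygote library. Its isolation and library preparation stay open, and no biological explanation was tested.

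Other splits of the libraries were refitted to see how many calls regrouping gives, with 10 splits for each pair of groups, which are too few for a share under 0.05. Sperm against egg gave 15876 genes against at most 2 in the other splits, 12 h zygotes against eggs 8912 against 6, 24 h against 12 h zygotes 248 against 1, apical cells against 24 h zygotes 5916 against 0 and basal cells against them 4276 against 0, each with 1 of 10 splits as large. Apical against basal cells gave 0 genes in all 10 splits by edgeR. In the real split 1267 genes were at an unadjusted p under 0.05, near the share of 0.05 passed without any difference, and DESeq2 called 75 and voom 9. The detection results gave 282 genes against 0 and 57 against 1, each with 1 of 10 splits as large. Every other split mixed the groups, so the detection rules could hardly be met and a real difference counted as spread within groups. The low numbers of genes in the other splits were thus largely fixed in advance. List calls were 6 against 7 in sperm and egg (3 of 10 splits as large), 19 against 10 in 12 h zygotes and eggs (1 of 10), 6 against 7 in 24 h and 12 h zygotes (2 of 10), 1 against 10 in apical cells and zygotes (10 of 10), and 6 against 10 in basal cells and zygotes (4 of 10). For the 5 genes that rose and then fell, 5 of 100 splits of the 9 libraries gave as many, the real one included, or 4 of 100 in a first draw that counted mirrored splits separately. The limit set beforehand was under 0.05 of the splits, which 5 of 100 does not meet, so chance was not excluded for the 5 genes. The other 4 put all 3 eggs (2778 and 2653 genes) or all 3 of the 24 h zygotes (78 and 67 genes) in the middle position. They thus kept a real group together, so the count of splits also reflects differences between the groups.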
